A study of Arabidopsis thaliana with 4 samples.

How the data were processed

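Seeds of Arabidopsis thaliana, Columbia 0, were germinated on half-strength Murashige and Skoog medium with 0.1% sucrose at 22 to 24 °C under 16 h of light and 8 h of dark, with or without ASP, and seedlings were taken at 5 days, per the labels' protocols. The dose of ASP was not given in the sources used here. Total RNA was purified with an RNeasy kit, and biotin-labelled cRNA was made with the GeneChip 3′ IVT PLUS kit and hybridised to Affymetrix arrays, per the labels' protocols. The scanner, the summary method and the software were not given in the sources used here.

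The authors deposited a workbook of normalized log2 signal per probe set, with a detection call of present, marginal or absent, per the file headers. The 2% trimmed mean of the linear signal was 500.0 on each array, and the median log2 signal ran from 7.503 to 7.530. The deposited series matrix held the same log2 values, with a largest difference of 5e-09. The authors also deposited a table of differing probe sets with an unadjusted t-test p-value and a ratio of group means of the linear signal (fold change), per the file headers. That p-value and ratio came from 3 columns per group. In the workbook, 4 columns of per-sample values, 2 of them log2 signal, matched no sample of the series by name and were not used here. Arrays were assigned to control and ASP from their titles and descriptions.

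The 64 Affymetrix control probe sets were set aside, which left 22746 probe sets. The annotation in the workbook assigned 21450 of them to 1 gene, 1110 to several and 186 to none. Only probe sets of 1 gene were named, which gave 21226 genes, 217 of them with more than 1 probe set, for which the brightest stood for the gene. Of these genes 21052 were found by locus in the reference gene table of assembly TAIR10.1, which was used for names only. No other probe set of a named gene went in the opposite direction.

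The values were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, two-sided, no replicate block), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Counts were also made at 2-fold, a log2 fold change of 1. The residual degrees of freedom were 2 and the prior degrees of freedom 1.34, and 6.06 with the intensity trend. Where a gene was called absent on both arrays of its dimmer group only, its fold is a bound: the mean of the brighter group against the mean, over the dim group's arrays, of the higher of its own signal and the lowest signal of any present probe set on that array. This bound allows for the detection limit only and not for the spread between arrays, so a fold given as "at least" sets no lower limit for other arrays. Genes called absent on all 4 arrays were given no fold. Values are printed as mean ± SD of log2 signal, and log2 fold changes are ASP minus control.

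Gene lists and cell type markers were fixed before the data were examined, as were the tests and the first set of alternative settings. Some genes stood in several lists, so the lists are not independent of each other. Of 1203 entries in 42 lists, 994 matched 1 measured gene, 68 matched none, 40 matched several and 101 belonged to genes without a probe set of their own. The 41 lists with at least 5 measured members were tested with camera on 1 probe set per gene, two-sided, with a preset correlation of 0.01 and adjustment over lists. Gene ontology terms of the workbook with 10 to 300 measured genes were tested by a one-sided Fisher's exact test against 19766 genes with a term, with adjustment over 2668 combinations of term and direction. Because fewer than 20 genes were called in a direction, genes with an unadjusted p under 0.01 and at least a 2-fold change were used, as fixed beforehand.

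The rule for named genes took the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, at least a 2-fold change, groups that did not overlap and a mean in the higher group above the median of all probe sets (7.51). If fewer than 5 passed, it took the 10 with the smallest p that met the other conditions, which 58 higher and 62 lower genes did. It also took up to 4 members with the smallest p from each list.

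The first alternative settings were a replicate block, the intensity trend, a robust variance prior, leaving out the dimmest 30% of probe sets, quantile normalization, median centring, the series matrix values, leaving out each array in turn, a plain t-test, an estimated correlation, fry, the mean over a gene's probe sets, and for terms a background without dim probe sets and calls at 2-fold. Alternatives with probe sets present on at least 2 arrays (15645), with linear values under 50 set to 50, and with the trend in further combinations were added after the data were seen. The median within-group SD of log2 signal was 1.198 for probe sets under a mean of 4 and 0.110 for those at 10 and over, so dim probe sets were measured less precisely. The fits were tested on simulated data in 5 runs of 22746 probe sets with 200 changed, and camera in 20 runs with 41 lists of 28 genes, where a list shifted by 0.25 was called in 14 runs and one shifted by 0.50 in 20, with 0 false lists. Those lists were simulated without correlation among genes. The term test found a planted term in 20 of 20 runs and called 1 term among random genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.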

Results

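Transcript levels were measured with Affymetrix 3′ expression arrays in whole 5-day-old seedlings of Arabidopsis thaliana, accession Columbia 0. The seedlings had grown on half-strength Murashige and Skoog medium either without ASP (control) or with it. ASP is the name the submitters gave to a synthetic sulfonylpiperazine that carries a bromophenoxyacetyl group. Each of the 2 groups held 2 arrays, which the labels call biological replicates. P-values of single probe sets measure the spread among these 4 samples. Those of camera with a preset correlation, of terms and of marker sets compare genes with genes, not samples with samples. Of 22746 probe sets tested, 15415 and 15282 were called present on the control arrays and 15075 and 15706 on the ASP arrays. Over the 14261 probe sets present on all 4 arrays, the correlation across probe sets was 0.9835 between the control arrays and 0.9845 between the ASP arrays. Between arrays of different groups it ran from 0.9732 to 0.9796. Over all probe sets the arrays of a group were not closer than the groups, with 0.947 and 0.945 within groups and 0.942 to 0.947 between them. Over those present on all 4 arrays, the median absolute log2 difference was 0.172 and 0.175 within groups and 0.171 to 0.219 between them. Probe sets are not independent replicates, and the small number of arrays limits the precision of every value.

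The comparison of ASP with control asks which transcripts differ in seedlings grown on the compound. GH3.3 (AT2G23170), which encodes an enzyme that conjugates the auxin indole-3-acetic acid to amino acids, was 9.74-fold higher with ASP, at a log2 signal of 12.02 ± 0.00 against 8.73 ± 0.06 in control (SD, n = 2 each). WES1 (AT4G27260, also known as GH3.5), of the same enzyme family, was 4.77-fold higher, at 11.62 ± 0.24 against 9.37 ± 0.20 (SD, n = 2 each). In the opposite direction, PCC1 (AT3G22231), a small protein under pathogen and circadian control, was 15-fold lower on these arrays. Its log2 signal was 10.43 ± 0.46 in control, with absent calls on both ASP arrays (6.52 ± 0.15, SD, n = 2 each). That fold is a bound for the detection limit only and no lower limit, since the authors' deposited table gave an 8.54-fold lower level. LBD41 (AT3G02550), a LOB-domain transcription factor known as a low-oxygen response gene, was 4.12-fold lower, at 9.99 ± 0.13 against 12.03 ± 0.13 (SD, n = 2 each). IRT1 (AT4G19690), the main iron uptake transporter of the root epidermis, was 3.53-fold lower, at 6.97 ± 0.14 against 8.79 ± 0.22 (SD, n = 2 each).

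None of these differences passed limma's test over all probe sets without a trend, in which the smallest Benjamini-Hochberg adjusted p was 0.265. Because no gene passed, the 10 genes with the smallest p in each direction are named as the fixed rule provides, and their adjusted p ran from 0.265 to 0.373. Besides GH3.3 and WES1, the higher genes were AT2G19970, annotated as a putative pathogenesis-related protein (7.54-fold), AT3G51410 (3.26-fold), AT3G28220 (3.18-fold), AT3G19200 (2.6-fold), AT2G37030 (2.51-fold), the gibberellin-regulated peptide gene GASA5 (2.49-fold), the BTB and TAZ domain gene BT5 (2.32-fold) and the oxysterol-binding protein gene ORP4C (2.2-fold). Besides PCC1, LBD41 and IRT1, the lower genes were SRO5, related to the stress regulator RCD1 (at least 6.14-fold), the DNA-binding protein gene AT3G10040 (5.42-fold), AT5G20790 (4.85-fold), the wound-responsive family members AT4G33560 (4.65-fold) and AT4G10270 (4.45-fold), AT5G39890 (4.11-fold) and AT2G28780 (2.98-fold). AT2G19970 was called present on neither control array. In all 20 genes both ASP arrays lay on the same side of both control arrays, as the rule required. Over all probe sets this held for 8966, or 39.4%, where a random order of 2 against 2 arrays gives 33.3%.

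**Figure D1:**
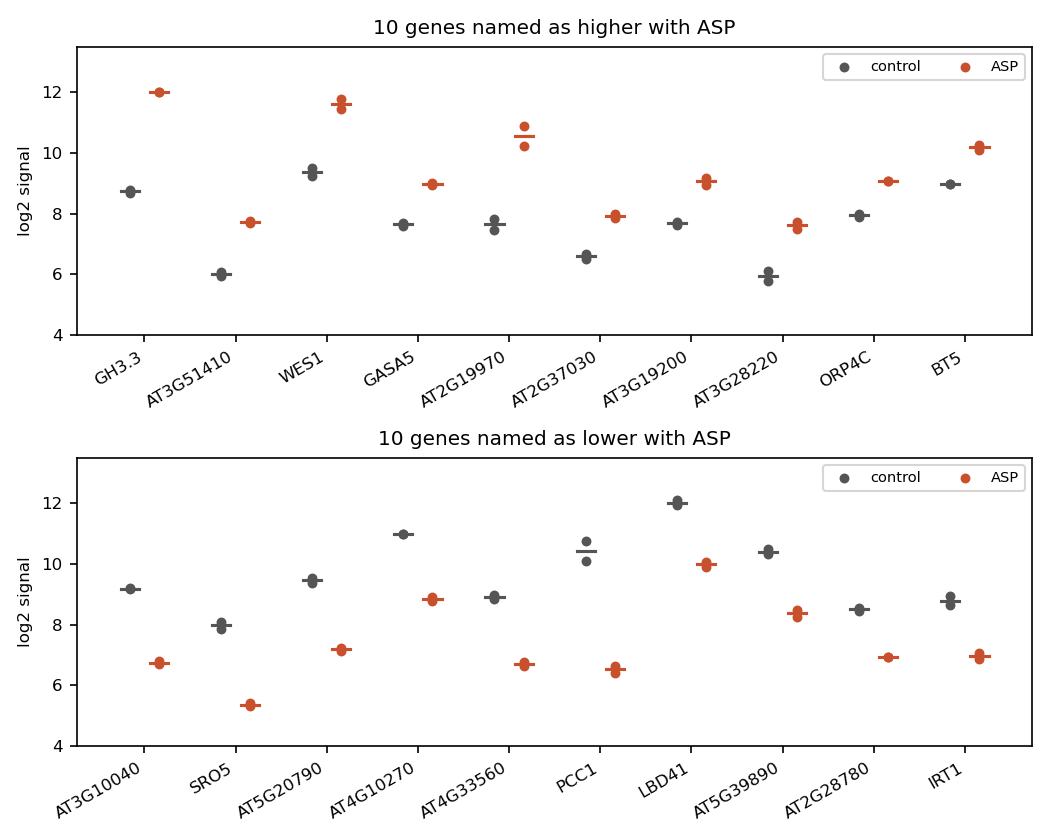
Log2 signal (y axis) of the 20 named genes (x axis) on each array, with the 10 higher genes above and the 10 lower genes below. Points are the 2 control and 2 ASP arrays, and bars are group means, and in every gene the groups do not overlap.

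At an adjusted p under 0.05, limma without a trend called 0 of 22746 probe sets. At an unadjusted p under 0.05 there were 1688 probe sets, 757 higher and 931 lower with ASP, and 871 of them differed by at least 2-fold, 349 higher and 522 lower. After quantile normalization the 2-fold split turned to 449 higher and 405 lower. An unmoderated test with equal variances, the kind named in the authors' deposited table, also called 0 after adjustment, with 1638 at an unadjusted p under 0.05. The planned limma fit with a prior variance that follows brightness (the intensity trend) called 72 probe sets, 34 higher and 38 lower. That number was 22 without control replicate 1, 37 without control replicate 2, 11 without ASP replicate 1 and 9 without ASP replicate 2. In data simulated with the spread of these arrays, the fit without a trend recovered 0% of the changed probe sets even at a log2 change of 3, and the trend fit recovered 52.4% at a log2 change of 1 and 100% at 3, with 39 false calls among 862. The simulated spread followed brightness, as the trend fit assumes, so the comparison of the fits favours the trend. Changed probe sets were drawn from those above the median control signal, so the recovery does not cover dim ones.

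**Figure D2:**
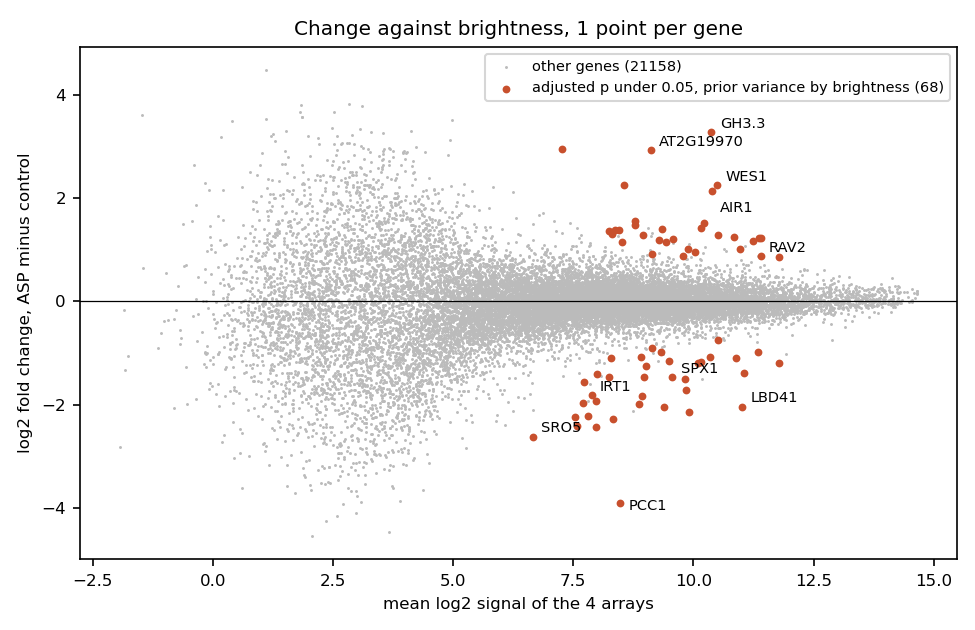
Log2 fold change of ASP over control (y axis) against the mean log2 signal of the 4 arrays (x axis), 1 point for each of 21226 genes. The 68 coloured genes, 32 higher and 36 lower, had an adjusted p under 0.05 in the limma fit with an intensity trend, and dim genes at the left scatter widely around 0.

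With the intensity trend, 17 of the 20 named genes passed, at adjusted p from 2.46e-05 for GH3.3 to 0.0261 for ORP4C. The other 3, AT3G51410, AT3G28220 and AT2G37030, had adjusted p of 0.0584, 0.0842 and 0.0847. Several other genes among the 72 calls, chosen after their values were seen, concern auxin. DFL1, also called GH3.6, was higher by a log2 fold change of 1.24, IAGLU, a glucosyltransferase acting on indole-3-acetic acid, by 1.42, AIR1, first described as auxin-induced in roots, by 2.13, the PINOID-binding protein gene PBP1 by 1.38, and the auxin repressor gene IAA7 by 0.85. The pathogenesis-related gene PR-1-LIKE was at least 7.73-fold higher. Among the lower calls, likewise picked afterwards, were AT4G33070, annotated as pyruvate decarboxylase 1 (log2 fold change -2.24), the tonoplast water channel gene TIP2;2 (-1.38) and the annotated peroxidase genes AT3G01190, AT5G19890, AT4G11290 and AT4G30170 (-1.99, -1.84, -1.15 and -1.07).

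Of the 41 gene lists tested, all fixed before the data were examined, 17 shifted at an adjusted p under 0.05 by limma's camera with a preset inter-gene correlation of 0.01, 9 upward and 8 downward. With an estimated correlation none of the 17 passed, and the smallest adjusted p over all lists was then 0.541. No member of any list was called over all genes without a trend, so the counts of members below are counts of direction, with the calls adjusted over the list alone beside them. Within the lists, 7 calls held whichever array was left out, those of ethylene, photosystem, auxin-responsive, phosphate, iron, circadian and chlorophyll genes.

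The auxin-responsive list rose, with 20 of 28 measured members higher and a median log2 fold change of 0.35 (camera adjusted p 2.61e-05, and adjusted p = 0.541 with an estimated correlation). Of its members 6 rose adjusted over the list alone, besides IAA20, which passed as lower but was absent on all 4 arrays, and with the intensity trend 8 rose and 1 fell on that basis, of which 3 also passed over all genes. After GH3.3 and WES1, the members with the smallest p were the lateral root transcription factor genes LBD29 and LBD18, which were at least 4.34-fold and at least 4.66-fold higher, with absent calls on both control arrays. The list of auxin synthesis, inactivation and transport did not shift (18 of 35 higher, camera adjusted p 0.425). Its members with the smallest p were the nitrilase gene NIT3 (log2 fold change -0.91), the efflux carrier gene PIN7 (0.72), the auxin methyltransferase gene IAMT1 (at least 1.73-fold higher) and the auxin synthesis gene YUC6 (at least 1.37-fold lower).

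The ethylene list also rose, with 26 of 31 members higher and a median of 0.40 (camera adjusted p 9.11e-07, and adjusted p = 0.541 with an estimated correlation). No member passed adjusted over the list alone without the trend and 10 rose with it, and 1, RAV2, passed over all genes with the trend. RAV2, a transcription factor of the ethylene-responsive EDF group, was 1.84-fold higher, the receptor gene ERS2 2.13-fold, and the response factor genes ERF104 and ERF6 2.55-fold and 1.8-fold. Brassinosteroid genes rose less clearly, with 14 of 20 higher and a median of 0.27 (camera adjusted p 0.0304, and adjusted p = 0.541 with an estimated correlation). The synthesis gene DWF4 was higher by 0.42 and the response genes BEE3 and BEE1 by 0.71 and 0.36, while the synthesis gene CYP90D1 had a log2 fold change of -0.42. With the trend 1 member rose adjusted over the list alone, and 0 without it. This call was lost after quantile normalization (adjusted p 0.0707) and without control replicate 2 (0.195), ASP replicate 1 (0.284) or ASP replicate 2 (0.0648).

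Abscisic acid response genes rose, with 22 of 32 higher and a median of 0.14 (camera adjusted p 0.0108, and adjusted p = 0.545 with an estimated correlation). Of the 32, 21 were called present on at least 2 arrays. RD26, a drought-induced transcription factor, was 2.22-fold higher and passed over all genes with the trend, and the phosphatase gene ABI1 and the catabolic genes CYP707A3 and CYP707A2 were 1.49-fold, 1.41-fold and 1.90-fold higher. Without the trend 0 members passed adjusted over the list alone, and 2 rose with it. Without control replicate 2 this adjusted p was 0.292, and without ASP replicate 1 it was 0.273. Xenobiotic detoxification genes rose too, with 29 of 45 higher and a median of 0.17 (camera adjusted p 0.0253, and adjusted p = 0.541 with an estimated correlation). The cytochrome P450 gene CYP81D11 was 2.96-fold higher and passed over all genes with the trend, and NAC102, the glutathione transferase gene GSTU16 and the glucosyltransferase gene UGT73B4 were 1.6-fold, 1.62-fold and at least 1.68-fold higher. With the trend 4 members rose adjusted over the list alone, and 0 passed without it. The call was lost without control replicate 1 (adjusted p 0.25), ASP replicate 1 (0.148) or ASP replicate 2 (0.0659).

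All 32 photosystem and light-harvesting genes measured were higher with ASP, with a median log2 fold change of 0.21 (camera adjusted p 9.11e-07, and adjusted p = 0.545 with an estimated correlation). The photosystem gene PSAN was 1.25-fold higher, PSBO2 of the oxygen-evolving complex 1.26-fold, and the Calvin cycle genes SBPASE and PRK both 1.27-fold. Of 21 chlorophyll synthesis genes 19 were higher, with a median of 0.19 (camera adjusted p 0.00122, and adjusted p = 0.541 with an estimated correlation), among them the regulator GLK2 (0.55) and the enzyme genes CHLM (0.37), GUN5 (0.33) and HEMA1 (0.31). Adjusted over the list alone, 0 members of either list passed, with or without the trend. Differences of similar size, none past adjustment, were measured in control probe sets: 37 of 42 spike-in probe sets were higher with ASP, with medians of 0.16 for 18 hybridisation and 0.27 for 24 labelling controls, and all 6 probe sets at the 5′ end of actin, GAPDH and ubiquitin were lower, with a median of -0.19. The circadian clock list rose with 17 of 23 higher and a median of 0.25 (camera adjusted p 0.00104, and adjusted p = 0.541 with an estimated correlation), 0 passing adjusted over the list alone without the trend and 5 rising with it. COL2, BBX19, PRR5 and COL1 were higher by 0.84, 0.85, 0.70 and 0.60. The markers of leaf mesophyll and guard cells did not shift (8 of 15 higher, camera adjusted p 0.480). Among them the carbonic anhydrase genes CA1 and CA2 and the Rubisco activase gene RCA were higher by 0.52, 0.34 and 0.29. The guard cell anion channel gene OZS1, absent on 3 of the 4 arrays, was at -0.55.

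**Figure D3:**
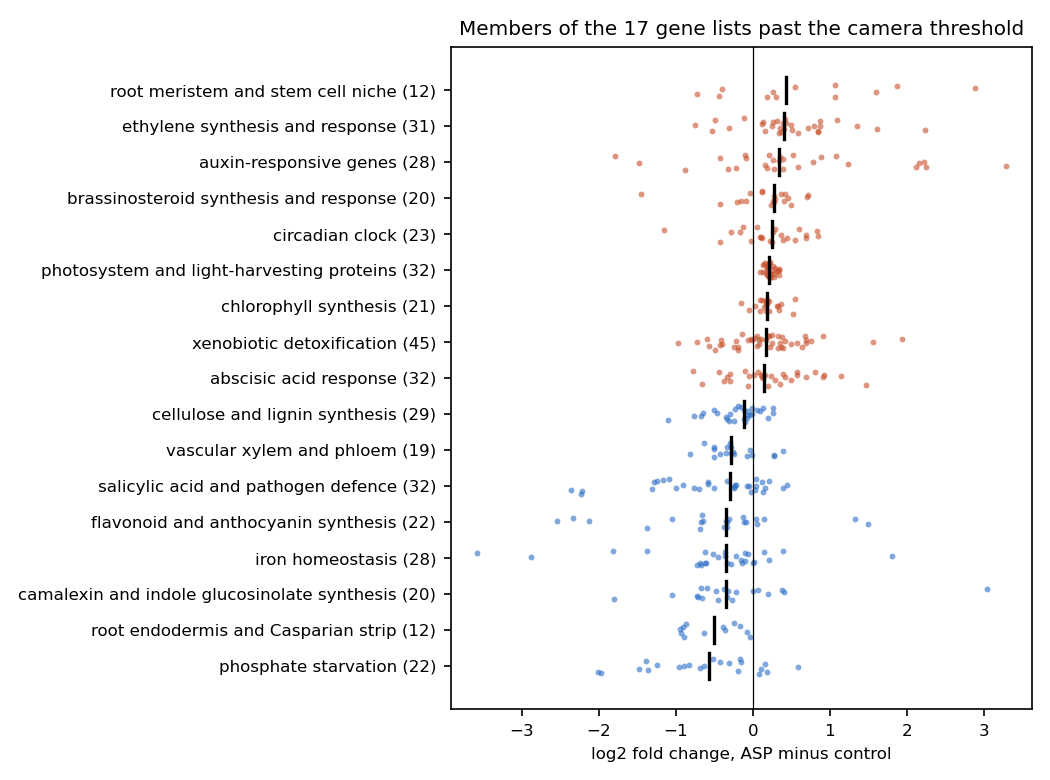
Log2 fold change of ASP over control (x axis) of every measured member of the 17 lists past the camera threshold (y axis, number of members in brackets), 1 point per gene. Vertical bars are list medians, from -0.57 for phosphate starvation to 0.43 for the root meristem, and lists of lower median are blue. Members called absent are included.

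Among lists of mineral nutrition, those of phosphate and iron fell. Of 22 phosphate starvation genes 17 were lower, with a median of -0.57 (camera adjusted p 2.84e-05, and adjusted p = 0.541 with an estimated correlation). Only 12 of the 22 were called present on at least 2 arrays, so the count and the median include genes near background. Of the members 2 fell adjusted over the list alone without the trend and 4 with it, and 2 passed over all genes with the trend: the phosphate sensor gene SPX1, 2.78-fold lower, and the acid phosphatase gene PAP17, 2.38-fold lower. PHO1;H1, related to the phosphate exporter PHO1, was 1.77-fold lower, and the transporter gene PHT1;8 was called absent on all 4 arrays. Of 28 iron homeostasis genes 22 were lower, with a median of -0.35 (camera adjusted p 0.000803, and adjusted p = 0.541 with an estimated correlation). Among them 1 fell adjusted over the list alone without the trend and 6 passed as lower with it, 1 of these the absent MYB10, and IRT1 passed over all genes with the trend. The vacuolar metal transporter gene MTPA2 was 2.59-fold lower and the nicotianamine synthase gene NAS2 1.53-fold, while MYB10, a regulator, was absent on all 4 arrays. The lists of nitrate assimilation (16 of 26 lower, camera adjusted p 0.335) and sulfate assimilation (12 of 20 lower, 0.938) did not shift. In the nitrate list RFNR2, NRT1.1 and G6PD3 had log2 fold changes of -0.46, -0.45 and -0.37 and GLU1 of 0.43, and in the sulfate list SERAT2;1, SULTR1;2 and APR2 had 0.44, -0.54 and -0.36, with BGLU28 absent on all arrays.

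Many of these nutrient genes are expressed in root tissues. Markers of the endodermis, root hairs and root cortex had medians below 0, and those of the meristem and root cap above 0. All 12 endodermis and Casparian strip markers were lower, with a median of -0.51 (camera adjusted p 0.00794, and adjusted p = 0.541 with an estimated correlation), and the genes CASP1, CASP2 and CASP4, which build the Casparian strip, were 1.83-fold, 1.93-fold and 1.86-fold lower, and CASP5 at least 1.87-fold. Without ASP replicate 2 the adjusted p was 0.152. Root meristem markers rose, with 9 of 12 higher and a median of 0.43 (camera adjusted p 0.0170, and adjusted p = 0.541 with an estimated correlation). UPB1, a regulator of the onset of differentiation, was 2.09-fold higher and AIL6, a PLETHORA family gene, 2.1-fold, while AGL42 and WIP4, with 2 of the 3 largest differences, were absent on all 4 arrays. The root stem cell regulators PLT1 and PLT2 and the peptide gene CLE40, picked after their values were seen, were the 3 lower members (log2 fold changes of -0.72, -0.40 and -0.44), and 8 of the 12 markers were present on at least 2 arrays. Without ASP replicate 2 that adjusted p was 0.208. Adjusted over the list alone, 0 endodermis and 3 meristem markers passed without the trend, 1 of them the absent AGL42, and 0 and 2 with it. Root hair markers (16 of 24 lower, median -0.15, camera adjusted p 0.315) and root cortex transcripts (10 of 14 lower, median -0.23, 0.134) did not pass. The root cortex list passed as lower with the intensity trend (adjusted p 0.0412), without dim probe sets (0.0470) and without control replicate 2 (0.0284), and the root hair list without control replicate 2 (0.0132). RHS18, AGP3, XTH14 and SCN1 had log2 fold changes of -0.53, -0.56, -0.48 and 0.29, and the aquaporin gene TIP2;3, DIR6, the boron channel gene NIP5;1 and the nitrate transporter gene NRT2:1 of -1.94, -0.73, -0.38 and -0.58. The 3 measured root cap markers had a median of 0.17 and were too few to test, CEL5 and FEZ being at least 1.23-fold and at least 1.12-fold higher and BFN1 absent throughout. For FEZ the log2 fold change was 0.17 with a standard error of 0.52 in limma with the trend.

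Vascular markers fell, with 16 of 19 lower and a median of -0.29 (camera adjusted p 0.0170, and adjusted p = 0.541 with an estimated correlation). The xylem protease genes XCP1 and XCP2 were 1.76-fold and 1.41-fold lower, the cellulose synthase gene IRX3 1.42-fold and the laccase gene IRX12 1.26-fold. The call was lost with the intensity trend (adjusted p 0.0638) and without control replicate 1 (0.113), ASP replicate 1 (0.0596) or ASP replicate 2 (0.146). Cellulose and lignin synthesis genes fell as well, with 23 of 29 lower and a median of -0.12 (camera adjusted p 0.00853, and adjusted p = 0.541 with an estimated correlation). This list shares IRX12, IRX1, IRX3, CESA4 and LAC17 with the vascular markers, all lower, so these calls are not separate evidence. The ligase genes 4CL3 and 4CL2 were 2.14-fold and 1.38-fold lower and the laccase gene LAC11 1.69-fold. Without control replicate 1 the adjusted p was 0.192 and without ASP replicate 2 it was 0.0988. Adjusted over the list alone, 0 members of either list passed, with or without the trend. The cell wall loosening list did not pass (25 of 38 lower, camera adjusted p 0.175, and 0.0405 with the intensity trend), with XTH19 and EXLA2 at 1.06 and -0.66, XTH16 at -0.75 and EXPA12 at least 2.13-fold higher. Class III peroxidases did not pass either (4 of 6 lower, 0.0707), where PRX52 was at least 2.62-fold lower and Prx37, AT2G41480 and AT5G66390 had -0.46, -0.48 and -0.81.

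Flavonoid and anthocyanin genes fell, with 17 of 22 lower and a median of -0.34 (camera adjusted p 0.000379, and adjusted p = 0.541 with an estimated correlation). Adjusted over the list alone, 3 fell without the trend, and 5 fell and 1 rose with it. The anthocyanin synthesis genes UF3GT and DFR were at least 4.82-fold and at least 4.38-fold lower, the anthocyanin transport gene GSTF12 2.6-fold and the flavanone hydroxylase gene F3H 1.61-fold. Without control replicate 1 the adjusted p was 0.0518 and without ASP replicate 1 it was 0.0590. Salicylic acid and defence genes fell, with 23 of 32 lower and a median of -0.29 (camera adjusted p 0.00794, and adjusted p = 0.545 with an estimated correlation), a call lost without control replicate 2 (adjusted p 0.391). Of these 32 defence genes, 18 were called present on at least 2 arrays. The immune gene AIG1 was at least 4.64-fold lower and DMR6, which hydroxylates salicylic acid, 1.5-fold, and RLP23 was absent on all arrays. ACD6, not called present with ASP and not on both control arrays, was 2.37-fold lower. Camalexin and indole glucosinolate genes fell, with 14 of 20 lower and a median of -0.35 (camera adjusted p 0.00853, and adjusted p = 0.541 with an estimated correlation), a call lost without ASP replicate 1 (0.0590) or ASP replicate 2 (0.0747). The cytochrome P450 genes CYP83B1 and CYP81F3 were 1.6-fold and 1.66-fold lower, and CYP71A12 and CYP71A13 were absent throughout. Adjusted over the list alone, 0 defence and 0 camalexin members passed without the trend, and 0 and 2 with it.

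The other lists did not pass with all 4 arrays and all probe sets without the intensity trend. Some of the alternatives in which a list passed are given beside it, but not all. Among probe sets present on at least 2 arrays, an added setting, 5 uncalled lists passed, and 7 with the trend. Cytokinin-responsive genes had 16 of 27 members lower (camera adjusted p 0.207, and 0.0183 without dim probe sets), among them the response regulator genes ARR7, RR5 and ARR6 at -0.76, -0.69 and -0.82, with IPT7 at least 2.05-fold lower. Heat shock and folding genes had 16 of 22 lower (0.207, and 0.0488 with the trend), with HSP90.1, Fes1A and HSP101 at -0.66, -0.63 and -0.59 and DREB2A at 0.74. Aliphatic glucosinolate genes had 11 of 15 lower (0.233, and 0.0172 with the trend), with SOT17 and IMS2 at -0.60 and -0.25, AOP2 at 0.27 and MYB76 absent. Sugar response genes had 19 of 30 higher (0.175), with BT2, SUS3 and TPS8 at 0.55, 0.58 and 0.58 and BAM5 absent. Oxidative stress genes had 19 of 31 higher (0.240), with MDHAR at -0.99, ZAT6 and RHL41 at 0.72 and 0.63 and AOX1D absent. Suberin and cutin genes had 18 of 30 higher (0.295, and 0.0134 without control replicate 1), with CER1, FAR4, ABCG2 and KCS2 at 0.44, 0.97, 0.54 and 0.85. Cold, wounding and touch genes had 16 of 24 higher (0.357), with CML38 and RAP2.6 at -1.47 and -1.06, STZ at 0.83 and GolS2 absent, and CML38 passed over all genes with the trend.

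Ribosome genes had 12 of 17 members lower (camera adjusted p 0.425), with NUC-L1, FIB2, RPL23AB and NUC-L2 at -0.29, -0.35, -0.20 and -0.43. Shoot apex markers had 13 of 18 lower (0.425), with AS2, CLV1 and AIL5 at -0.28, -0.29 and -0.56 and STM at least 1.29-fold higher. Sterol and isoprenoid genes had 16 of 29 lower (0.480), with SMT3, CPI1, HMGS and XF1 at -0.49, -0.56, -0.47 and -0.26. Gibberellin genes had 14 of 27 higher (0.739), with GA2OX6, RGL2 and GID1B at 0.59, -0.77 and -0.48 and GA1 absent. Cell cycle genes had 23 of 38 lower (0.739), with AUR2, LGO, CYCB1;1 and MCM5 at 0.50, 0.51, 0.40 and -0.32. Jasmonate genes had 16 of 30 lower (0.886), with AOC3, ST2A and JAZ3 at -0.66, 0.74 and -0.40 and TAT3 at least 3.23-fold lower. DNA damage genes had 8 of 15 higher (0.938), with ATLIG4, AT4G19130, BRCA1 and ATRAD17 at 0.33, -0.32, -0.25 and -0.30. In the DNA damage and sulfate lists the median, the mean and the test differed in sign. Dry seed transcripts (13 of 23 lower, 0.564) and pollen and flower genes (4 of 5 higher, 0.585) were mostly absent. Of the named CRU2, M10, ATS1, AGP11, AGP6 and AP3 none was present on any array, while CRU3 was called on some arrays, at -0.93. PI, also called on some arrays, was higher by a bound of 1.13-fold, but its direction turned in an alternative setting. Of these uncalled lists, adjusted over the list alone without the trend, 1 class III peroxidase gene fell, PRX52, and 0 passed in the others apart from M10 and CRU2, whose signal was called absent. With the trend, on the same basis, 3 peroxidase genes fell, as did 2 root cortex, 2 cytokinin and 2 heat shock genes and 1 aliphatic glucosinolate gene. Calls with the trend went both ways in auxin synthesis, inactivation and transport (3 higher, 1 lower), oxidative stress (2 and 1), cell wall loosening (1 and 2), nitrate (1 and 2) and cold, wounding and touch (1 and 1), and 1 jasmonate gene rose.

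Over-representation of gene ontology terms was tested among genes with an unadjusted p under 0.01 and at least a 2-fold change, 124 higher and 169 lower, because no gene was called. Of 1334 terms, 5 passed a one-sided Fisher's exact test after adjustment. Response to hypoxia held 8 of its 65 genes among the lower ones (adjusted p 0.000108), among them LBD41, AT4G33070, AT3G10040 and FTM1. Response to cyclopentenone held 10 of 121 genes among the higher ones (adjusted p 1.23e-05), among them WES1, DFL1, LBD29, PBP1 and CYP81D11. The terms for regulation of hydrogen peroxide metabolism (9 of 125, adjusted p 0.00115) and systemic acquired resistance (9 of 190, 0.0217) among the lower genes held the same 8 hypoxia genes plus LURP1. Floral organ abscission held 4 of 31 among the higher genes (0.0217), BT5 among them. No term passed without control replicate 1, control replicate 2 or ASP replicate 1, where the hypoxia term had adjusted p of 1.00, 0.297 and 0.372, and without ASP replicate 2 there were 2, hypoxia and hydrogen peroxide metabolism, both at 0.0297.

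The authors' deposited table listed 148 probe sets at an unadjusted p under 0.05 and at least a 2-fold change, 66 higher and 82 lower with ASP. Its test used 3 columns per group, of which 2 per group are analysed here. All 148 probe sets of the authors' deposited table had the same direction here, and 119 of them also met both thresholds in the limma fit without a trend. Of the 72 calls made with the intensity trend, 48 were in the authors' deposited table. Of the genes named here, 9 of the 10 higher and 5 of the 10 lower ones were in the authors' deposited table, which did not list LBD41, AT3G10040, SRO5, AT4G10270 and AT4G33560. For GH3.3 the authors' deposited table gave a 9.63-fold higher level with ASP, with p = 1.86e-07, and for PCC1 an 8.54-fold lower level, with p = 0.0257, less than the bound of 15-fold from the arrays used here. The shared arrays mean that these overlaps are not independent evidence.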

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

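Every alternative named here as added was chosen after the data were seen, and the others were planned. The count of probe sets called at an adjusted p under 0.05 was 0 without a trend and stayed 0 with the replicate block, a robust prior, quantile normalization, median centring, the series matrix values, a plain t-test and each array left out. It was 72 with the intensity trend and 18 with dim probe sets left out, and among added alternatives 321 with the trend and replicate block, 22, 37, 11 and 9 with the trend without control replicate 1, control replicate 2, ASP replicate 1 and ASP replicate 2, 19 for probe sets present on at least 2 arrays, 193 with the trend on those, and 8 with values under 50 set to 50. Fewer probe sets were tested in those filtered settings, and otherwise the cause was not tested. All 72 were among the 321 and among the 193. The count at an unadjusted p under 0.05 and 2-fold, 871, was 1034 with the replicate block and 1300 to 1431 with an array left out (1 group then holds a lone array, assumed to vary like the others). It was 217 without dim probe sets, 432 by plain t-test, and in added settings 234, 226 with the trend (both present on at least 2 arrays) and 176 with the floor of 50. The replicate numbers did not pair the arrays: deviations of same-numbered arrays had a correlation of 0 over all probe sets and -0.024 over those present throughout, and without the trend the replicate block left 17 lists called and changed no list or named gene call. With the trend it raised the named genes called from 23 to 55 and the lists from 20 to 22. The 17 lists called became 20 with the trend, 20 without dim probe sets, 16 after quantile normalization, 10 to 16 with an array left out, 0 with an estimated correlation and 1 by fry, which asks whether members move one way (camalexin and indole glucosinolate synthesis, adjusted p 0.0293). No called list turned its direction in any alternative, while 13 uncalled lists and 3 of 183 named genes (BFN1, AP3 and PI) did in at least 1. The 5 terms became 14 pairs of term and direction without dim probe sets (13 terms, as xylem development passed in both directions), which also took the higher and lower genes tested from 124 and 169 to 44 and 46, and in added settings 17 and 16 with the trend (by unadjusted p and by calls). Of the 5, 4 passed in these 3 settings, and floral organ abscission did not (adjusted p 0.223 without dim probe sets). The count was 0 to 2 with an array left out, 2 without ASP replicate 2. Calls at 2-fold gave terms no separate value, since 0 genes were called, and the lists were not tested with the robust prior. With the trend 23 of the 183 named genes passed and 160 stayed uncalled.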

Other observations

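The low-oxygen gene list, the tests of root share and harvest time, the test of scaling for low-oxygen genes, and the clock subsets below were chosen after results were seen. A list of 44 loci known to respond to low oxygen, 43 of them measured, was lower as a set: 38 members were lower with ASP, 32 of them with groups that did not overlap (33.3% of genes would separate in either direction in random order), and the median log2 fold change was -0.48 (camera p = 2.12e-16, p = 0.0115 with an estimated correlation, and 8.38e-13 to 1.40e-10 with 1 array left out). With the intensity trend 14 members passed over all genes, and adjusted over the list alone 16 passed without the trend and 19 with it. LBD41 was 4.12-fold lower, SRO5 at least 6.14-fold, AT4G10270 4.45-fold and FTM1, a stearoyl-ACP desaturase family gene, 2.66-fold. Of fermentation genes, AT4G33070, annotated as pyruvate decarboxylase 1, was 4.71-fold lower. ADH1 and PDC2 were lower by 1.28-fold and 1.35-fold and did not pass. Of the 43 genes 4 were also in the fixed lists. The list includes genes whose values prompted it, such as LBD41, so its p-values overstate the evidence. The authors' deposited table, whose test used 3 columns per group, listed 5 of the 43 genes and 4 of the 14, and LBD41, SRO5 and AT4G10270 were not among them, which speaks for caution about this pattern.

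The auxin-type pattern was followed into 237 genes that the workbook annotates as responding to auxin and that stood in no fixed list. They shifted upward (144 higher, camera p = 0.00396), which is consistent with an auxin-type response to ASP as a hypothesis, but the shift had p = 0.19 with an estimated correlation and p = 0.166 without control replicate 2. Of 10000 random lists of the same size and brightness, 0% had a median as high as the auxin-responsive list (0.35 against at most 0.25). That speaks only against a rise shared by all genes of that brightness, since random lists lack the correlation among auxin-responsive genes. Whether ASP acts like an auxin or changes auxin levels was not tested.

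For the low-oxygen pattern, 6204 genes of the same brightness that were not picked had a median of -0.01. Random lists drawn at that brightness had medians no lower than -0.17. These values speak only against a fall shared by all genes of that brightness. The arrays had the same trimmed mean beforehand, and the list was written after its values were seen, so random lists could hardly match it. A smaller share of root tissue stays open as a part of the fall of these genes. The 42 low-oxygen genes called present on at least 2 arrays had a median of -0.46, and that of 10 endodermis markers was as low (-0.51, permutation p = 1.00), while 12 root cortex markers had -0.23 (permutation p = 0.132) and 20 root hair markers -0.17 (permutation p = 0.0105). Because the list was written after its values were seen, these comparisons exclude nothing. That the change reflects oxygen supply or its sensing may be proposed, and it stays open too. The 69 further genes annotated to hypoxia gave limma's camera p of 0.577. That set left out every gene of the low-oxygen list, among them all 8 lower genes of the hypoxia term. It was thus stripped of genes already seen to fall, and its p decides nothing.

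For the higher photosystem genes and lower endodermis markers, a smaller share of root tissue stays open: 20 root hair markers had a median of -0.17 and 10 endodermis markers -0.51 (permutation p = 0.0254), but the permutation p was 0.24 without control replicate 2 and 0.14 without ASP replicate 2. The root meristem list rose with all 4 arrays, with PLT1 and PLT2 lower, and its call was lost without ASP replicate 2. That list was no part of this comparison, so it decides nothing about the share of root tissue. An earlier time of day at harvest could raise morning genes and lower evening genes, and 10 morning clock genes, 8 of them already in the fixed lists, had a median of 0.38 against 0.05 for 7 evening genes, a difference with an exact p of 0.166. No evening gene was lower with groups that did not overlap and 2 were higher, PRR5 (0.70) and TOC1 (0.12), but with 4 higher and 3 lower the set decides nothing, and harvest time and treatment cannot be told apart. RNA quality and an effect of ASP on plastid or root development stay open and were not tested. Of 10000 random lists of the same size and brightness, 0% had a median as high as the photosystem genes (0.21 against at most 0.15). That speaks only against a rise shared by all genes of that brightness. Random lists lack the correlation among photosystem genes, and hybridisation spike-in controls had a median of 0.16, so a technical part of the rise stays open.

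The 5′ control probe sets had log2 fold changes of -0.39 and -0.23 for actin, -0.35 and -0.15 for GAPDH and -0.11 and -0.11 for ubiquitin, while the 6 at the 3′ end ranged from -0.08 to 0.11. In limma with the trend 2 of the 5′ ones had unadjusted p under 0.05 (0.0138 for actin and 0.024 for GAPDH), and none passed after adjustment (smallest adjusted p 0.365). Of the spike-in controls, 17 of 18 for hybridisation (-0.04 to 0.31) and 20 of 24 for labelling (-0.30 to 0.58) were higher with ASP, none at an unadjusted p under 0.05. Spike-ins on an array share its scaling factor, so these counts are not a test.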
